A study of Mus musculus with 8 samples.

How the data were processed

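MicroRNAs (miRNAs) were profiled in mouse bone marrow cells sorted as Lin-cKit+Sca1+ (LSK), the fraction that holds haematopoietic stem and early progenitor cells. Per the labels, the mice were 10-week-old C57BL/6 females carrying floxed Tsc1, 4 with the Mx1-Cre transgene (Tsc1 cKO) and 4 Cre-negative littermates (Ctrl). The design text also mentions conditional alleles for inactivating Raptor, while the genotype labels name Tsc1 alone, and Tsc1 was used here. All received 400 µg of pIpC (2 mg/ml), an inducer of Mx1-Cre, in 7 injections, and cells were taken 10 days after the last one. Each sample is a biological replicate per the labels.

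Per the labels, the authors extracted total RNA with TRIzol, labelled 5 µg per sample with a biotinylated random octamer primer, hybridised it to a 1-colour miRNA array and detected it with streptavidin-Alexa647 on an Axon scanner. The deposited values of both tables, one for mature and one for precursor probes, are in units of intensity, on a linear scale. The file comment, a template text, calls them normalized (scaled) signal. The scaling method, the treatment of background and any filter are not given in the sources used here. All values were checked to be positive multiples of 0.5. A further table of the series was checked to equal the mature table in every cell and added nothing. The arrays had not been brought to a common level, since their medians differed, and many probes of each array shared one low level, taken here as the background.

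Values were transformed to log2(value + 1), and probes with the same name were averaged. The mature table gave 433 names from 521 probes and the precursor table gave 274 names from 300 probes. Probes are named in the text without the mouse prefix and the suffix for mature or precursor form. The 4 names in the precursor table whose probes read both forms (6 probes) stayed in the precursor fit and were left out of the match of forms. The background of an array was the mode of its log2 values over both tables, and a probe is called bright where its mean lay more than 1 log2 unit above that level. By this measure 94 mature and 34 precursor names were bright, and the number of arrays limits the precision. The median standard error of a log2 fold change was 0.26 for mature and 0.23 for precursor probes, and 0.40 for bright mature probes. Fold changes are Tsc1 cKO minus Ctrl.

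Tests used R 4.3.3 with limma 3.58.1 (lmFit and eBayes, no block, Benjamini-Hochberg threshold 0.05), fitted within each table. The mature and precursor forms of 264 miRNAs were matched by name. Numbered genomic copies of 1 miRNA, such as let-7c-1 and let-7c-2, count apart here and in the lists. The per-sample differences of the log2 values of both forms were tested in the same way. The method of normalization of the 2 tables is not given in the sources used here. Their background levels differed by 0.022 to 0.052 log2 units on every array, and this is why the difference was tested. Medians of arrays and means of miRNA groups were compared with 2-sided exact permutation tests over all 70 assignments of the 8 samples, whose smallest p is 0.0286. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

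miRNA lists were written before the data were examined. They held the let-7 and miR-98 family, the clusters of miR-17 and its paralogues miR-106a and miR-106b, miRNAs enriched in haematopoietic stem cells (HSC-enriched), Hox-cluster miRNAs, miRNAs made without Drosha or DGCR8, p53-regulated miRNAs and interferon- or NF-kB-responsive miRNAs. They also held the family of miR-15, miR-16, miR-195 and miR-497, the clusters of miR-23, miR-27 and miR-24, the miR-29, miR-30 and miR-181 families, the pair of miR-221 and miR-222, Myc-repressed miRNAs, the imprinted Dlk1-Dio3 miRNAs, the Sfmbt2 intron cluster and pan-haematopoietic miRNAs. Marker lists covered erythroid, myeloid, lymphoid, megakaryocyte, stromal or endothelial, and non-haematopoietic cells. Of these 23 lists, 22 had at least 3 mature probes and 19 had at least 3 precursor probes and were tested. The tests were camera with a preset correlation of 0.01, camera with an estimated correlation, and fry, each adjusted over the lists. fry asks whether the members of a list move one way on balance and does not compare them with other probes. Members were also adjusted over the list alone.

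The rule for naming probes was set before the data were examined. It took up to 10 risers and 10 fallers past the threshold in each table or, where none passed, the 5 with the smallest unadjusted p. It also took up to 4 mature members of each list, the 2 highest and the 2 lowest. Probes named outside this rule are marked as chosen after their values were seen.

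The methods were tested on simulated data with the spread of these arrays. With 40 changed probes in each of 50 simulated data sets, limma recovered 50.5% of changes of 1 log2 unit among mature probes and 90.4% of changes of 2 units, and 73.1% and 96.7% among precursor probes. The share of false calls lay between 4.07% and 5.34%. In these runs the noise was drawn independently for each probe, with no brightness difference between arrays, so these shares may not hold for the real arrays. With no true change and the probe correlations of the arrays kept, camera with the preset correlation called at least 1 mature list in 70% of the simulated data sets. The corresponding shares were 0% with an estimated correlation and 4.0% with fry. In these runs the brightness difference fell at random over the groups, while it is balanced in the real arrays. These shares may therefore not hold for the real arrays either.

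Alternatives set before the data were examined were a block for replicate number, centring of each array on its median, quantile normalization, a filter on the lowest 25% of probes, a pseudocount of 16, and mouse-named probes alone. The others were a trended and robust eBayes, array weights, the further table of the series, star probes left out of the lists, the omission of each sample in turn, and the samples whose labels give the scanner as 4000B. Alternatives chosen after seeing the data were a block for a difference in array brightness between samples 1-2 and 3-4, each of these sets of samples alone, subtraction of the background (values under 10% of it set to 10%), bright probes alone, and lists without their let-7 members. Samples with the same number in both groups were checked for pairing by the correlation of their residuals, which lay between 0.0927 and 0.348 for mature and -0.0341 and 0.144 for precursor probes. The mature values leave a pairing open. The main fit takes the numbers as unpaired, and the block for replicate number is the paired alternative. No genome position was needed, and the current RefSeq gene symbols served only to look up names. Raw images were not used here.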

Results

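miRNA levels were measured on arrays in LSK cells of 4 Tsc1 cKO mice and 4 Ctrl littermates, 1 array per mouse. Tsc1 is a negative regulator of mTORC1, the kinase complex that couples growth to nutrients, and the title of the series concerns mTORC1 and miRNA biogenesis. The comparisons therefore cover mature miRNAs, their precursors, the balance between both forms, and the level of each array as a whole. The probes read miRNAs, so the deletion of Tsc1 itself was not analysed here. The design text of the series also mentions conditional alleles for inactivating Raptor, a part of mTORC1 whose loss would lower rather than raise its activity; the genotype labels name Tsc1 alone and were followed. Total mature intensity per array lay between 27732800 (Tsc1 cKO 4) and 63876700 (Ctrl 2), and total precursor intensity between 11344400 (Tsc1 cKO 4) and 20313100 (Ctrl 1). Samples 1 and 2 of both groups were brighter than samples 3 and 4, with a mean median mature intensity of 35368.5 against 26563. These sets hold 2 mice of each group, so values within each set are given below as those of samples 1-2 and samples 3-4. Tsc1 cKO 4 stood apart with a narrow range of signal: 74 of its mature probes were bright, against 93 to 112 on the other arrays.

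**Figure D1:**
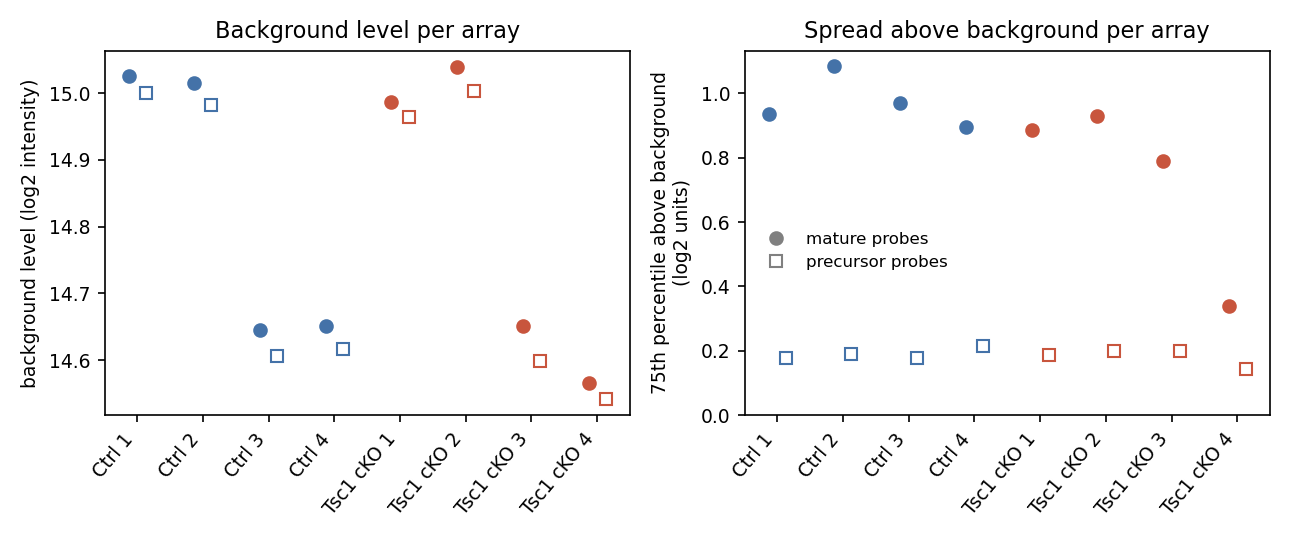
Background level (left, log2 intensity) and 75th percentile above that level (right, log2 units) of each array, for mature probes (filled circles) and precursor probes (open squares), Ctrl in blue and Tsc1 cKO in red. Samples 1 and 2 of both groups have the higher background, and Tsc1 cKO 4 has a mature 75th percentile of 0.34, against 0.79 to 1.09 on the other arrays.

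Mature let-7, a family that restrains proliferation and accumulates as cells differentiate, was lower in Tsc1 cKO than in Ctrl LSK cells. Of its 13 probes 12 had a negative log2 fold change, with a median of -0.83, and the median was negative in each of 24 alternatives, scaling included. Some of these probes are for genomic copies of 1 miRNA, such as let-7c-1 and let-7c-2, so they are not 13 separate miRNAs. let-7c-1 stood at 18.22 ± 0.42 in Ctrl and 17.21 ± 0.44 in Tsc1 cKO (log2 intensity, SD, n = 4 each), 2.00-fold lower, and let-7c-2 (log2 fold change -1.03, SE 0.41) and let-7a-2 (-1.01, SE 0.41) had fold changes of similar size. let-7i had -0.43 (SE 0.27), and miR-98, which lay at background, 0.12 (SE 0.39). The family passed camera with the preset correlation (adjusted p = 3.22e-08), with adjusted p = 0.835 with an estimated correlation and 0.624 by fry. Of its members, 2 passed when adjusted over the list alone (let-7c-1 and let-7d*-3p) and 0 when adjusted over all mature probes. In Tsc1 cKO let-7d*-3p lay only 0.16 log2 units above background, so the size of its fold change is uncertain. Set against the median of its own array, the mean of the family was 2.06 ± 0.21 in Ctrl and 1.38 ± 0.42 in Tsc1 cKO (log2, SD, n = 4 each), and all 4 Tsc1 cKO mice lay below all 4 Ctrl mice. The exact permutation p for this difference of -0.69 was 0.0286, the smallest that 4 against 4 mice can give, and 0.314 after adjustment over the 22 lists. The array median reads mostly background, so it does not correct for a shift shared by bright probes. Of the bright mature probes 76 were lower and 18 higher, with a median log2 fold change of -0.24. As deposited, the mean of the let-7 family differed by -0.73 with an exact permutation p of 0.0857. The median fold change was -0.82 in samples 1-2 and -0.83 in samples 3-4, and -0.46 without Tsc1 cKO 4, and with these sets as a block the family had adjusted p = 5.40e-07 by camera, adjusted p = 0.494 with an estimated correlation and 0.139 by fry.

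miRNAs enriched in haematopoietic stem cells were also lower, 20 of 22 probes with a median log2 fold change of -0.67. Among them were copies of miR-125b, which expands stem cells when overexpressed: miR-125b-2 had -1.40 (SE 0.49), and miR-125b-1 stood at 15.79 ± 0.49 in Ctrl and 14.56 ± 0.63 in Tsc1 cKO (log2 intensity, SD, n = 4 each). In Tsc1 cKO neither was above background (means of -0.48 and -0.23 log2 units relative to it, against 0.89 and 0.96 in Ctrl), so the size of these fold changes is uncertain. miR-155 (0.01, SE 0.46) was not lower. Of the miR-196a probes, 1 had 0.45 (SE 0.36) but lay at -0.29 log2 units relative to background, and miR-196a-1, 0.63 above background, had -0.67 (SE 0.31). The list had adjusted p = 2.05e-06 by camera with the preset correlation, adjusted p = 0.835 with an estimated correlation and 0.624 by fry. No member passed when adjusted over the list alone, nor over all probes, and limma gave 6 members at unadjusted p under 0.05. The megakaryocyte list (miR-126, miR-99a, miR-125b, miR-224) shares 7 of its 8 probes with this list and had a median of -0.97, with 7 probes lower, among them the star arm miR-126*-5p (-1.04, SE 0.50). That probe stood at a log2 intensity of 13.44 in Tsc1 cKO 4, against 15.42 to 15.87 in the other Tsc1 cKO mice, so 1 mouse carries much of its size. miR-126-3p (-0.17, SE 0.24) and miR-224 (0.02, SE 0.20) lay near 0. Both were close to background (0.20 and -0.06 log2 units relative to it), so these values say little on the 2 miRNAs. The megakaryocyte list had adjusted p = 7.99e-05 by camera with the preset correlation, adjusted p = 0.835 with an estimated correlation and 0.624 by fry. Of its members 1, miR-125b-1, passed when adjusted over the list alone, against 0 over all probes. Per mouse, against the array median, the megakaryocyte list differed by -0.78 (exact permutation p = 0.0286, 0.314 adjusted over the 22 lists) and the HSC-enriched list by -0.56 (exact p = 0.0857). As for let-7, the adjusted value cannot decide. Only 6 of the 22 HSC-enriched and 1 of the 8 megakaryocyte probes were bright. The medians were -0.47 in samples 1-2 and -0.81 in samples 3-4 for the HSC-enriched list and -0.67 and -1.21 for the megakaryocyte list, and the HSC-enriched median was -0.36 without Tsc1 cKO 4. With these sets as a block camera gave adjusted p = 5.40e-07 and 2.85e-04, with adjusted p = 0.476 and 0.460 with an estimated correlation and 0.0903 and 0.0608 by fry. Among bright probes alone the HSC-enriched call ended (adjusted p = 0.362).

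The 3 further lists that passed camera with the preset correlation were the Myc-repressed, miR-29 and Hox-cluster miRNAs, all with negative medians. By fry none of them passed (adjusted p = 0.728 for the Myc-repressed list and 0.624 for the other two). Of 31 probes for miRNAs that Myc represses, 29 were lower (median -0.44, adjusted p = 7.99e-05, and 0.835 with an estimated correlation), and miR-150, a regulator of lymphoid maturation, stood at 16.31 ± 0.49 in Ctrl and 15.46 ± 0.15 in Tsc1 cKO (log2 intensity, SD, n = 4 each). All 5 miR-29 probes, which also belong to the Myc-repressed list, were lower (median -0.55, adjusted p = 0.0330, and 0.835 with an estimated correlation), miR-29a by a log2 fold change of -0.90 (SE 0.54). For miR-29a it was -0.13 in samples 1-2 and -1.68 in samples 3-4, with Tsc1 cKO 4 the lowest mouse at a log2 intensity of 13.82. Of the 8 Hox-cluster probes 7 were lower, with a median of -0.55 (adjusted p = 0.0468, and 0.835 with an estimated correlation) that was 0.10 in the samples labelled with scanner 4000B alone, where brightness and group mix. miR-615 had the lowest value of this list, -0.89 (SE 0.24), and miR-10b had -0.19 (SE 0.42). In simulated data with no true change, camera with the preset correlation called at least 1 mature list in 70% of 50 data sets. Brightness fell at random over the groups in these data sets and is balanced in the real arrays, so the share may differ there. Of the 18 splits of the 8 mice that balance samples 1-2 and 3-4, the real one included, 5 called at least 6 mature lists. Adjusted over the list alone, 1 Hox-cluster probe (miR-615) passed and 0 of the others, and 0 passed over all probes. Together the 6 lists held 57 probes, 51 of them lower, a share that follows in part from the choice of lists called lower. Of all mature probes 64.9% were lower, and of the bright ones 76 were lower and 18 higher. The lists overlap: 7 Myc-repressed probes are let-7 and 7 Hox-cluster probes are HSC-enriched. Without its let-7 members the Myc-repressed list had a median of -0.34 and adjusted p = 0.0518. Medians in samples 1-2 and 3-4 were -0.37 and -0.56 for the Myc-repressed, -0.42 and -0.37 for the miR-29 and -0.38 and -0.58 for the Hox-cluster list. The calls ended in samples 3-4 alone for all 3 lists (adjusted p = 0.0645, 0.193 and 0.0811) and in samples 1-2 alone for the miR-29 (0.345) and Hox-cluster list (0.0921). Quantile normalization ended the miR-29 (median -0.30, adjusted p = 0.182) and Hox-cluster calls (-0.40, 0.0868) and gave a median of -0.21 for the Myc-repressed list (adjusted p = 0.00492). A block for these sets gave adjusted p of 7.50e-04, 0.103 and 0.0143 by camera and 0.821, 0.821 and 0.476 with an estimated correlation. Among bright probes alone the Myc-repressed and Hox-cluster calls ended (adjusted p = 0.362 for both). Omission of 1 mouse ended the Hox-cluster call in 4 cases (adjusted p = 0.218 without Ctrl 2, 0.0799 without Ctrl 3, 0.0680 without Tsc1 cKO 1 and 0.129 without Tsc1 cKO 3) and the miR-29 call in 3 (0.102 without Ctrl 2, 0.0874 without Ctrl 3 and 0.341 without Tsc1 cKO 2). Without Tsc1 cKO 4 the medians were -0.14 for the Myc-repressed, -0.29 for the miR-29 and -0.33 for the Hox-cluster list. Without Ctrl 2 the Myc-repressed median was -0.25, the miR-29 median -0.37 and the Hox-cluster median -0.28, without Tsc1 cKO 1 the miR-29 median was -0.84, and without Tsc1 cKO 3 the Hox-cluster median was -0.34. In the other cases where a call ended the medians were -0.68 (without Ctrl 3) and -0.65 (without Tsc1 cKO 1) for the Hox-cluster and -0.62 (without Ctrl 3) and -0.42 (without Tsc1 cKO 2) for the miR-29 list. Omission of a mouse also leaves the groups unequal in brightness, so these changes cannot be assigned to the mouse alone.

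**Figure D2:**
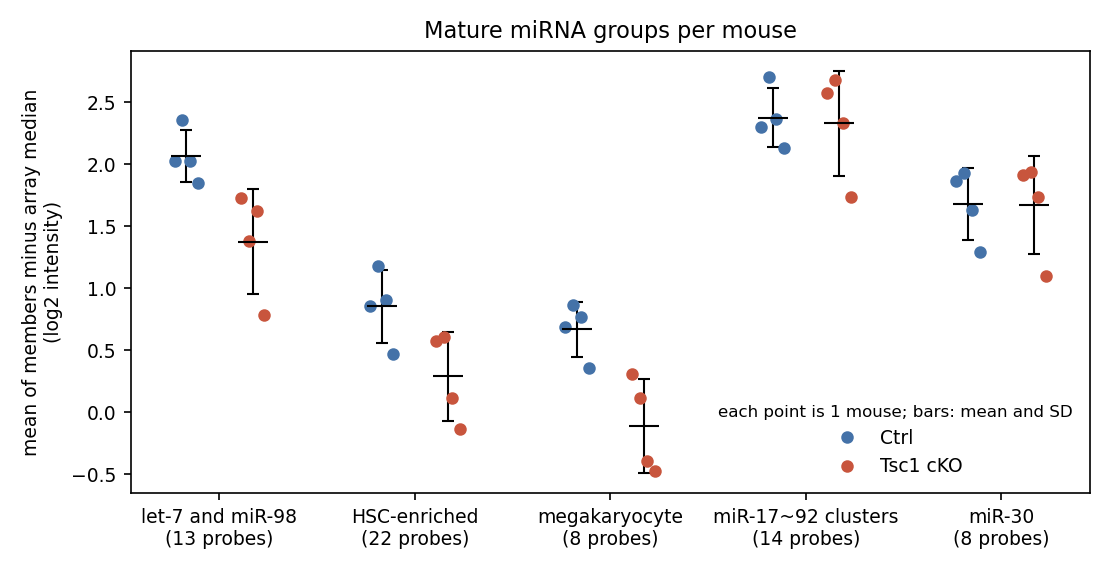
Mean log2 intensity of the mature members of 5 lists minus the median of the array, 1 point per mouse, with mean and SD of 4 Ctrl (blue) and 4 Tsc1 cKO mice (red). In the let-7 and megakaryocyte lists all Tsc1 cKO mice lie below all Ctrl mice, while the group means of the clusters of miR-17 and its paralogues (2.37 and 2.33) and of the miR-30 family (1.68 and 1.67) lie close together.

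No single mature probe passed the threshold. limma gave 0 of 433 at adjusted p under 0.05 (lowest adjusted p = 0.605) and 19 at unadjusted p under 0.05, of which 17 were lower and 2 higher, where 21.7 would come by chance. The 5 with the smallest p were all lower: miR-615, encoded within a Hox cluster, let-7d*-3p, miR-125b-1, let-7c-1 and miR-668. miR-615 was bright and stood at 18.71 ± 0.28 in Ctrl and 17.83 ± 0.35 in Tsc1 cKO (log2 intensity, SD, n = 4 each), 1.85-fold lower. let-7d*-3p, the passenger strand of let-7d, had a log2 fold change of -0.85 (SE 0.24) and miR-668 of -0.88 (SE 0.27). In Tsc1 cKO these 2 probes lay only 0.16 and 0.30 log2 units above background, so the size of their fold changes is uncertain. In samples 1-2 and samples 3-4 the fold changes were -0.97 and -0.81 for miR-615, -1.14 and -0.56 for let-7d*-3p, -1.25 and -1.20 for miR-125b-1, -1.08 and -0.92 for let-7c-1, and -1.04 and -0.71 for miR-668. The groups did not overlap for 4 probes, all lower in Tsc1 cKO, a share of 0.924%. Chance would give 2.86% if brightness played no part, but brightness widens both groups and makes overlap more likely. With the brightness sets as a block, limma gave 0 probes at adjusted p under 0.05 and 38 at unadjusted p under 0.05 (lowest adjusted p = 0.292). With replicate number as a block, limma gave 0 and 48, 45 of the 48 lower (lowest adjusted p = 0.0581).

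The other 16 tested lists did not pass. miRNAs of the cluster of miR-17 and its paralogues, which drive proliferation and which Myc induces, had a median of -0.10 over 14 probes (adjusted p = 0.670), with miR-93 at -0.39 (SE 0.43) and miR-19b-2 at 0.30 (SE 0.36). Of the miRNAs made without Drosha or DGCR8, 4 of 5 were lower (median -0.31, adjusted p = 0.243): miR-668 passed when adjusted over the list alone, while miR-484 had -0.50 (SE 0.55), miR-320 -0.27 (SE 0.21) and miR-344 0.34 (SE 0.43). The median of this list was -0.11 without Tsc1 cKO 4 (3 of 5 lower) and -0.10 after quantile normalization. Among blood-cell lists the median was -0.36 for the pan-haematopoietic list (14 of 17 lower, adjusted p = 0.0682), -0.36 for lymphoid markers (7 of 9 lower, adjusted p = 0.0682), -0.36 for the miR-181 family (adjusted p = 0.320) and -0.41 for myeloid markers (adjusted p = 0.530). Without Tsc1 cKO 4 these 4 medians were 0.0074 (8 of 17 lower), -0.06, -0.06 and -0.04, and after quantile normalization -0.07, -0.07, -0.07 and -0.19. The myeloid miR-223 had -0.27 (SE 0.67), and miR-222 and miR-221, a pair too small to test as a list, had -0.61 (SE 0.36) and -0.61 (SE 0.47). Erythroid markers had a median of 0.03 (adjusted p = 0.318), with miR-451 at -0.28 (SE 0.25) and miR-144 at 0.03 (SE 0.21). Of the 3 erythroid probes 0 were bright. miR-451 and miR-144 lay at -0.18 and 0.03 log2 units relative to background, so their values say little on these miRNAs. miR-486, abundant in red cells, stood at 14.63 ± 1.02 in Ctrl and 15.97 ± 0.97 in Tsc1 cKO (log2 intensity, SD, n = 4 each, adjusted p = 0.902 by limma). In Ctrl it was not above background (mean of -0.20 log2 units relative to it), so the size of this difference is uncertain. p53-regulated miRNAs (median -0.05, adjusted p = 0.965), interferon- or NF-kB-responsive miRNAs (-0.04, 0.965), the family of miR-15, miR-16, miR-195 and miR-497 (-0.07, 0.965) and the clusters of miR-23, miR-27 and miR-24 (0.01, 0.872) lay near 0. So did the miR-30 family (-0.14, 0.932), the Dlk1-Dio3 miRNAs (-0.04, 0.872), the Sfmbt2 cluster (-0.12, 0.458), stromal or endothelial markers (-0.03, 0.965) and non-haematopoietic markers (-0.05, 0.872), of which 1 of 29 probes was bright. Bright probes were also few in the Dlk1-Dio3 (6 of 48), Sfmbt2 (1 of 7), stromal or endothelial (1 of 16), interferon- or NF-kB-responsive (2 of 12) and p53-regulated lists (4 of 14). In these lists a median near 0 reads mostly background. The miR-15 and miR-16 family (6 of 8), the clusters of miR-23, miR-27 and miR-24 (4 of 6) and the miR-30 family (5 of 8) had more. Of these 16 medians 2 changed sign after centring of the arrays, 8 after quantile normalization and 10 without Tsc1 cKO 4. Median, mean and camera direction differed in sign for 4 of them, those of miR-17 and its paralogues, of miR-23, miR-27 and miR-24, of miR-30 and of Dlk1-Dio3. Omission of 1 mouse brought the pan-haematopoietic list past the threshold in 3 cases (adjusted p = 0.00201 without Ctrl 4, 0.0366 without Tsc1 cKO 1 and 0.00892 without Tsc1 cKO 2), the lymphoid list in 2 (0.00353 without Ctrl 4 and 0.0439 without Tsc1 cKO 1) and the miR-181 family in 1 (0.0240 without Ctrl 4). Each omission leaves the groups unequal in brightness. The median fold change of all mature probes was -0.11 without Ctrl 4 and 0.06 without Tsc1 cKO 4. The calls and sign changes after an omission therefore cannot be assigned to the omitted mouse.

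**Figure D3:**
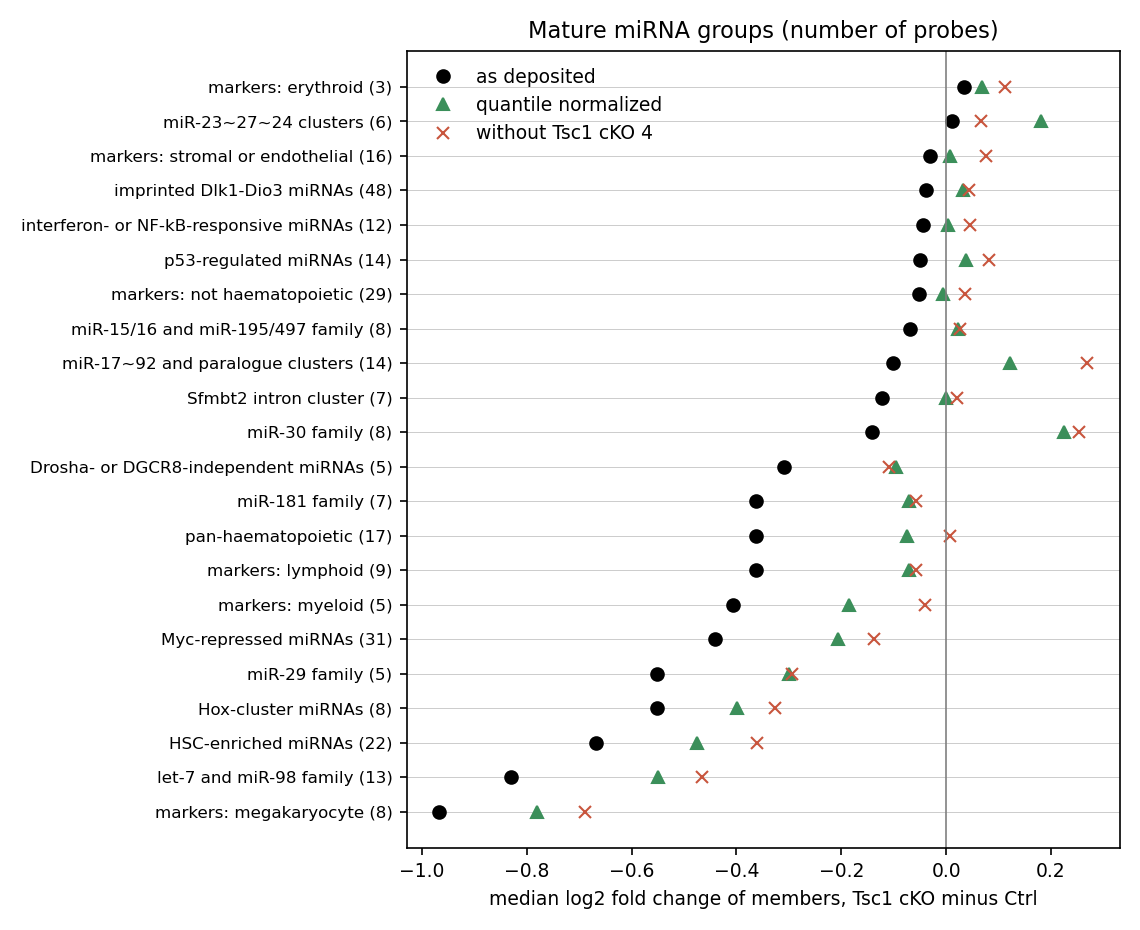
Median log2 fold change (Tsc1 cKO minus Ctrl) of the mature members of each tested list, with the number of probes, as deposited (black), after quantile normalization (green) and without Tsc1 cKO 4 (red). The medians of the 6 lowest lists stay below 0 in all 3 settings (let-7 at -0.83, -0.55 and -0.46), although the miR-29 and Hox-cluster lists no longer pass after quantile normalization, while 8 of the other 16 medians change sign after quantile normalization and 10 without Tsc1 cKO 4.

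Precursors were compared to ask whether miRNA genes were transcribed or trimmed differently. The precursors of let-7 had a median log2 fold change of -0.02 over 9 probes, those of HSC-enriched miRNAs -0.03 over 13, and none of the let-7 precursors was bright. The largest difference relative to its error was in the precursor of miR-375, a miRNA of endocrine cells, which stood at 17.70 ± 0.16 in Ctrl and 17.16 ± 0.17 in Tsc1 cKO (log2 intensity, SD, n = 4 each), 1.45-fold lower, with -0.48 in samples 1-2 and -0.60 in samples 3-4. Next came the precursors of miR-702 (-0.85, SE 0.35), miR-7-2 (-0.49, SE 0.20), miR-499 (-1.01, SE 0.42) and miR-34c (-0.71, SE 0.30), all at background on average. limma gave 0 of 274 precursor probes at adjusted p under 0.05 (lowest adjusted p = 0.999) and 7 at unadjusted p under 0.05, all lower. Chance would give 13.7 if brightness played no part, but here too the brightness difference stays in the error. With the brightness sets as a block the counts were 0 and 12. The groups did not overlap for 3 probes, 1.09%, where chance would give 2.86% if brightness played no part. None of the 19 tested precursor lists passed camera, the lowest adjusted p being 0.898 with the preset correlation, 0.995 with an estimated correlation and 0.954 by fry. All 19 medians were negative, from -0.33 (miR-29 family) to -0.01 (Dlk1-Dio3 miRNAs), but 7 changed sign after quantile normalization and 14 without Tsc1 cKO 4. That omission also leaves the groups unequal in brightness. Median, mean and camera direction differed in sign for 7 of the 19, the let-7 and HSC-enriched lists among them.

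The balance of mature and precursor form was compared for 264 miRNAs to ask whether processing differed. For let-7, 8 of 9 miRNAs, genomic copies counted apart, had a more negative fold change in the mature than in the precursor form, with medians of -0.83 and -0.02 and a median difference of -0.96. All 12 matched HSC-enriched miRNAs did so too (medians -0.74 and -0.04, median difference -0.78). Single examples are miR-668 (difference -1.15, SE 0.25) and let-7c-1 (-0.99, SE 0.26). The precursor of miR-668 lay at -0.14 log2 units relative to background and had a fold change of 0.27. Its mature form lay 0.30 above background in Tsc1 cKO, so the size of this difference is uncertain. For miR-125b-1 (-1.07, SE 0.28) the precursor stood 2.01 log2 units above background and had a fold change of -0.16, but the mature form was not above background in Tsc1 cKO, so the size of this difference is uncertain. limma gave 0 of 264 differences at adjusted p under 0.05 (lowest adjusted p = 0.328) and 18 at unadjusted p under 0.05, 15 of them lower and 3 higher, and 0 and 26 with the brightness sets as a block. A list test on the differences, added after the data were seen, gave adjusted p = 1.89e-05 for the HSC-enriched list by camera with the preset correlation, adjusted p = 0.154 with an estimated correlation and 0.0956 by fry. For let-7 it gave 4.65e-05, adjusted p = 0.462 with an estimated correlation and 0.167 by fry. The median difference was -0.96 in samples 1-2 and -0.83 in samples 3-4 for let-7 and -0.73 and -1.01 for the HSC-enriched list, and it stayed negative after quantile normalization (-0.64 for both lists) and without Tsc1 cKO 4 (-0.66 and -0.58). None of the 9 let-7 precursors and 2 of the 12 HSC-enriched precursors were bright, so most of these differences carry the mature change against a precursor signal at background. Of all 264 differences 140 were negative, and of the 13 miRNAs bright in both forms 5 had a negative difference.

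**Figure D4:**
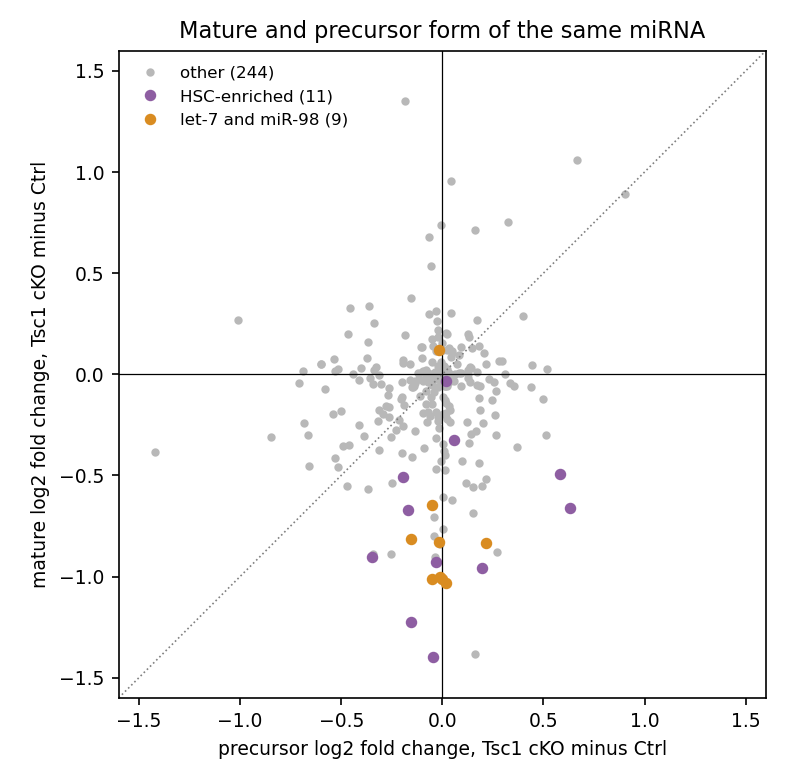
Log2 fold change (Tsc1 cKO minus Ctrl) of the precursor (x axis) and mature form (y axis) of 264 matched miRNAs, 1 point each, with let-7 and miR-98 in orange, HSC-enriched miRNAs in purple (let-7e shown with let-7) and all others in grey; the dotted line marks equal change. Of the 9 let-7 and miR-98 points 8 lie below 0 on the y axis, with a median of -0.83, and their precursor median is -0.02.

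No difference between the groups was detected in the level of mature miRNAs as a whole. The median mature probe stood at 14.91 ± 0.22 in Ctrl and 14.87 ± 0.25 in Tsc1 cKO (log2 intensity, SD, n = 4 each), a difference of -0.04 (exact permutation p = 0.714), with -0.03 in samples 1-2 and -0.06 in samples 3-4. The median precursor probe stood at 14.83 ± 0.22 and 14.80 ± 0.24, a difference of -0.03 (exact permutation p = 0.629), with -0.01 and -0.05. Since most probes lay at background, these medians read background more than miRNA. Among bright probes alone the difference was -0.38 for mature (exact permutation p = 0.486) and -0.24 for precursor probes (exact permutation p = 0.400). Among bright mature probes 76 were lower and 18 higher in Tsc1 cKO, and among bright precursor probes 25 were lower and 9 higher. The number of bright mature probes was 106 ± 4.97 per Ctrl and 92.8 ± 13.3 per Tsc1 cKO array (SD, n = 4 each, exact permutation p = 0.114), and the 75th percentile lay 0.97 ± 0.08 and 0.74 ± 0.27 log2 units above background (exact permutation p = 0.0571), differences of -0.10 in samples 1-2 and -0.37 in samples 3-4. Of all mature probes 64.9% were lower in Tsc1 cKO, and of all precursor probes 59.1%. The shares were 35.6% and 32.8% without Tsc1 cKO 4, and 42.3% and 47.1% after quantile normalization. They also crossed 50% without Ctrl 1 (48.3% and 42.7%), Ctrl 2 (47.1% and 42.0%) or Tsc1 cKO 3 (49.0% and 43.4%), and the median differences turned positive without any of these 4 mice, to at most 0.049 for mature and 0.054 for precursor probes (both without Tsc1 cKO 4). Each omission makes the groups unequal in brightness, which can itself move these values.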

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

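The let-7 tests other than its count over 35 splits, the splits balanced for brightness, and the test of the share of lower probes without Tsc1 cKO 4 were chosen after the results were seen; the counts over 35 splits were set before.

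Of 176 groups of 4 values checked for a sample far from the other three, 6 held one, where 8.8 would come by chance at 1 in 20. Mature miR-125b-1 was high in Tsc1 cKO 1 at a log2 intensity of 15.50, against 14.18 to 14.32 in the other Tsc1 cKO mice. miR-93 was low in Tsc1 cKO 4 at 15.65, against 17.06 to 17.23. miR-344 was low in Tsc1 cKO 4 at 14.04, against 14.89 to 15.02. miR-9-2-5p was high in Tsc1 cKO 2 at 15.10, against 14.61 to 14.67. miR-29b-1 was low in Ctrl 4 at 14.93, against 15.45 to 15.54 in the other Ctrl mice. miR-467a-3p was high in Ctrl 1 at 15.38, against 14.40 to 14.57.

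The lower mature let-7 signal was weighed against technical sources. The distance of the family from the median of all mature probes was 0.79 in the real split and at most 0.65 in the others, so 1 of 35 splits was as large, but these ignore the brightness of the arrays, and the 18 balanced over samples 1-2 and 3-4, with 0.65 as the highest other too, are too few for a share under 0.05. Array-wide differences in scale are argued against as the whole cause, since the mean of the family still differed by -0.48 after quantile normalization (SE between mice 0.12, exact permutation p = 0.0286, the smallest 4 against 4 can give). The narrow signal range of Tsc1 cKO 4 is argued against as the whole cause, since without that array the difference was -0.41 (SE 0.13, exact permutation p = 0.0286) after quantile normalization and -0.49 (SE 0.15, exact p = 0.0571) after centring, but part of it may stem from there, as deposited values gave -0.44 (SE 0.23, exact p = 0.171) without it and -0.73 with it. By their names, let-7a-1 and let-7a-2 are genomic copies of 1 miRNA, as are let-7c-1 and let-7c-2, so these probes do not count as separate members. For the other probes, several reading 1 let-7 RNA cannot be told apart from common regulation of the family. The residuals of the members correlated at 0.633 across arrays but at 0.447 with each array centred. An effect of Tsc1 loss on let-7 stays open.

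The excess of lower over higher mature probes cannot be told apart from an effect of Tsc1 cKO 4: without that array, with samples 1-2 and 3-4 as a block, 51.5% of the probes were lower in place of 64.9%, within the spread between mice of 15.2 points. Omission of 1 mouse also makes the groups unequal in brightness, and the share then lay between 35.6% and 82.2%. Chance cannot be excluded for the excess: the real share lay 14.9 points from 50% and 25 of the 35 splits lay as far. The highest other, 44.0 points, came from the split that follows the brightness of samples 1-2 against 3-4. Splits unbalanced in brightness can move the share by themselves. Among the 18 balanced splits, the real one included, 8 lay as far, with 23.9 points as the highest other, so chance cannot be excluded there either. An effect of Tsc1 loss on many miRNAs stays open as untested.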

How the results depend on the processing

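The brightness block, samples 1-2 and 3-4 alone, subtracted background, bright probes and lists without let-7 were chosen after seeing the data; estimated correlation and fry belonged to the original plan. limma gave 0 mature probes in 23 alternatives (lowest adjusted p 0.0529, 8 to 48 at unadjusted p under 0.05), 0 precursor probes in 22 (0.163, 0 to 20) and 0 differences in 22 (0.141, 1 to 29), and camera 0 precursor lists in 24 and fry 0. The replicate block gave 48 mature, 15 precursor and 29 difference probes at unadjusted p under 0.05 and 6 mature lists. These were not the same 6 as in the main fit, as the miR-29 call ended. Mature lists passing numbered 4 to 9 with 1 mouse left out, 3 in samples 3-4 alone, 1 among bright probes (13 lists tested, so fewer members), 0 with an estimated correlation and 0 by fry. let-7 passed in all 24 alternatives (medians -1.20 to -0.32) and megakaryocyte in all 23 (-1.92 to -0.35); HSC-enriched failed among bright probes, Myc-repressed in 3 alternatives, Hox-cluster in 10 (among them samples labelled 4000B, where its median reversed to 0.10) and miR-29 in 10. The share of lower mature probes was 42.3% after quantile normalization, 24.5% in samples labelled 4000B, 80.9% among bright probes and 35.6% to 82.2% with 1 mouse left out. The precursor share was 47.1% after quantile normalization, 23.4% in samples labelled 4000B, 78.1% with background subtracted, 73.5% among bright probes and 32.8% to 77.4% with 1 mouse left out. The mature median difference reversed to 0.17 in samples labelled 4000B and ran from -0.12 to 0.049 with 1 mouse left out; for precursors these were 0.18 and -0.10 to 0.054. Among bright probes it was -0.38 for mature and -0.24 for precursor probes. The samples labelled 4000B hold no Tsc1 cKO mouse of the dimmer set, so brightness and group mix there, and the label numbers run on from 4000B to 4002B by 1, so no scanner difference need lie behind them; elsewhere the cause was not tested. Of 1729 values of 78 named probes 117 changed sign, none of them past the threshold. Centring and quantile normalization fix the array median and gave no median difference, the mouse-name filter removed nothing, and signal over background limits all precursor values.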

Other observations

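The test on names without a RefSeq gene was made on a pattern noticed in the data, and the tests of arrays 4 and 2 and the splits balanced for brightness were chosen after the results were seen; the counts over 35 splits were set before.

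Of the 433 mature names, 13 had no current RefSeq miRNA gene, and 11 of these were higher in Tsc1 cKO (median 0.31), against 141 of 420 (33.6%) of the matched names. The count was 7 without Tsc1 cKO 2 (median 0.09), 8 without Ctrl 4 (0.13), 9 without Ctrl 3 (0.14) and 8 with background subtracted (0.09), where 16.7%, 17.6%, 21% and 18.8% of the matched names were higher. Without Tsc1 cKO 4 it was 11 (median 0.49, against 63.8% of the matched names). It was also 11 after centring of the arrays (median 0.35, against 49.0%) and after quantile normalization (0.38, against 56.9%), so the share of matched names depends on the scaling. The probes named here were chosen after their values were seen. miR-714, the brightest of them to be higher, stood at 19.19 ± 0.66 in Ctrl and 19.95 ± 0.42 in Tsc1 cKO (log2 intensity, SD, n = 4 each). miR-712-5p, whose sequence lies in the spacer of the ribosomal RNA precursor, had a log2 fold change of 1.11 (SE 0.55), and its other strand miR-712*-3p 0.98 (SE 0.40). miR-715 had 1.06 (SE 0.50), miR-805 0.68 (SE 0.59) and miR-689 -0.35 (SE 0.31). The set had p = 4.26e-06 by camera with the preset correlation, p = 0.106 with an estimated correlation and p = 0.374 by fry. In samples 1-2 and in samples 3-4, 10 of the 13 were higher (medians 0.49 and 0.13), and of 9 such precursor names 6 were higher (median 0.13).

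The distance of this set from the median of all mature probes was 0.35 in the real split and at most 0.32 in the others, so 1 of 35 splits was as large, but the set was noticed in the real split, so this says nothing on chance. Against the array median the mean of the 13 was higher in Tsc1 cKO by 0.44 (SE between mice 0.19, exact permutation p = 0.0857). Without Tsc1 cKO 4 the difference was 0.60 (SE 0.15, exact permutation p = 0.0286). That array has a narrow signal range and low values for the brighter probes of the set. Its omission could thus only raise the difference and does not test it as a cause. These p-values were computed on a set noticed in the same data. The bright Tsc1 cKO 2 cannot be told apart from a group effect, since without it the difference was 0.30 with an SE of 0.17 (exact p = 0.114). An effect of Tsc1 loss stays open as untested.

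The real split of the 8 samples into 4 and 4 gave 0 mature probes, 0 precursor probes, 0 differences between mature and precursor form and 0 precursor lists past the threshold, which each of the 35 splits reaches by definition, so these counts say nothing on chance. The highest others were 209 mature probes, 144 precursor probes, 1 difference and 1 precursor list. The first 2 of these came from the split of samples 1-2 against 3-4, which also gave 257 mature probes at unadjusted p under 0.05 against 19 in the real split, a count that 12 of the 35 splits reached, so chance cannot be excluded for it. Among the 18 splits balanced over these sets, too few for a share under 0.05, the highest other was 13. Splits that call this many probes point to a structure of the samples, the brightness of the arrays, and with that as a block limma gave 0 mature and 0 precursor probes at adjusted p under 0.05, with 38 and 12 at unadjusted p under 0.05. The real split called 6 mature lists and the highest other 9, and 6 of the 35 splits called as many, so chance cannot be excluded for this number. The lowest camera p of any mature list was 8.83 (let-7) on a scale of -log10 p in the real split and at most 7.36 in the others, so 1 of 35 was as low. These splits ignore the brightness of the arrays, and the 18 balanced splits, with 7.36 as the highest other too, are too few for a share under 0.05.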
